A study of Mus musculus with 2 samples.

How the data were processed

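H3K4me2 ChIP-seq peak lists from mouse hindbrain at embryonic day 11.5 were analysed, with 2 biological replicates in 1 group. The replicates were pools of 109 and 88 embryos, and the labels give a size range of 300 to 500 for both libraries. The authors deposited 4 peak lists in narrowPeak format on mm10, per the file headers and the accompanying notes: 1 for each replicate (44157 and 56250 peaks), 1 called on the alignments of both replicates together (38377 peaks), and a replicated list (29916 peaks) made from that pooled list and both replicate lists. Every replicated peak was an exact entry of the pooled list. Per the same deposited notes, peaks were derived from the alignments of the replicates and of control libraries, and those alignments were not among the files. The aligner, the peak caller and their versions are not given in the sources used here, and neither is the rule by which the authors kept a peak as replicated.

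Column 7 of the deposited lists holds the fold enrichment of each peak over control, a linear ratio, per the narrowPeak format. Columns 8 and 9 of the deposited lists hold the −log10 p-value and the −log10 q-value of each peak, and column 10 its summit. The lists are permissive: 2630 peaks of replicate 1, 7167 of replicate 2, 1093 of the pooled list and 102 of the replicated list had a q-value above 0.05. Fold enrichment depends on the depth of the sample and of its control, neither of which the files give. Breadth was measured in covered bases. No read totals, coverage tracks or alignments were used, so the depth of each library is unknown, folds were compared only between peaks of the same list and, as a correlation and a ratio, between the replicates, and intervals on shares of peaks or genes cover counting error only.

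Peaks on contigs outside chromosomes 1 to 19, X and Y (14, 15, 12 and 11 in the order above) were left out of the comparisons. Genes and TSSs came from the GENCODE vM21 basic annotation of GRCm38, the same assembly as mm10: 21938 protein-coding genes with 41492 distinct TSSs, and 77161 TSSs of genes of every type. Coordinates are 1-based. Each peak was placed by its midpoint, in order of priority, in promoter (within 1 kb of any TSS), 5′ UTR, 3′ UTR, coding exon, non-coding exon, intron or intergenic sequence. A gene was counted as marked when a peak overlapped the 1 kb either side of any of its TSSs. Breadth was the length under peaks within 5 kb either side of the 5′-most TSS. Distal peaks lay over 2.5 kb from any TSS and within 50 kb of that TSS. Domains were replicated peaks merged over gaps of up to 1 kb.

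The 20 gene lists, the tests and the rule for naming genes were chosen before the data were examined: Hox groups 1 to 4, 5 to 8 and 9 to 13, rhombomere and hindbrain patterning, midbrain and isthmus patterning, forebrain regulators, dorsoventral progenitor domains, neural stem and progenitor cells, hindbrain neuron regulators, general neuronal genes, late glia, endothelium, blood and immune cells, neural crest and mesenchyme, heart and skeletal muscle, liver and gut, germline, housekeeping, cell cycle, and retinoic acid and Shh signalling. All 396 distinct members were found in the annotation. Named genes were the 20 with the longest promoter domain that both replicates covered for at least 50%, the 3 broadest and 3 narrowest members of each list, the 10 with most distal peaks, a fixed set of marker genes, the nearest genes of the 10 strongest replicated peaks and of the 5 strongest unmatched peaks of each replicate, and members that went against their list where 5 or fewer did. The text names part of that set, and Hoxd1, Hoxd3 and a few further list members named as examples were chosen after their values were seen.

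Overlap of the replicates (at least 1 bp) and genomic location were set against 100 shuffles of peak positions within chromosomes (bedtools 2.31.1, fixed seeds, one-sided p, smallest value 0.0099). Promoter occupancy of each list was compared with all other protein-coding genes by a two-sided Fisher's exact test. Breadth and distal peaks of the marked members were compared with 100000 random lists of marked genes of the same size by a two-sided permutation test (smallest p 2e-05), for lists with at least 3 marked members. Benjamini-Hochberg adjustment ran over the lists of each test, and 0.05 was the threshold. Hox groups 1 to 4 were compared with groups 9 to 13, and the hindbrain list with the forebrain list, by Fisher's exact test and by permutation of the members. The correlation of fold between overlapping peaks was computed across peaks and given no p-value. Intervals are exact 95% Clopper-Pearson intervals (scipy 1.17.1). Python 3.11.15, numpy 2.4.6, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were also used.

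The list tests were checked on simulated data with 20 genes per list among the 21938 genes. They called higher occupancy in 40 of 40 lists set to 98%, lower occupancy in 39 of 40 lists set to 20%, and greater breadth in 40 of 40 lists with doubled breadth. Among unchanged lists, 0 of 120 were called for occupancy and 1 of 80 for breadth. Counts of shared peaks were the same as those from bedtools.

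Alternatives tried were the list of each replicate alone or the pooled list in place of the replicated list, peaks with a −log10 q of 5 or more, peaks at or above the median fold of their list, other overlap rules (50% of a peak, or 50% of both peaks), equal numbers of peaks per replicate, promoter windows of 500 bp and 2.5 kb, breadth windows of 2.5 and 10 kb, distal windows of 25 and 100 kb, the 5′-most TSS alone, a background without olfactory and vomeronasal receptor genes, random genes matched on the number of neighbouring TSSs, and domain gaps of 0 and 3 kb. Added after the data had been seen were shuffles that left out assembly gaps (100 or more N), a further recount of replicated peaks, random genes matched in deciles on the CpG observed to expected ratio within 500 bp of the 5′-most TSS, the same comparison with every member of a list counted as marked, the best-covered TSS of each gene, and the 93459 TSSs of every annotated transcript. Gene families by symbol, clustered protocadherins and summit positions were also examined after the data had been seen.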

Results

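Chromatin of the mouse embryonic hindbrain at day 11.5 of development was profiled by ChIP-seq for H3K4me2, histone H3 dimethylated at lysine 4, a modification found at promoters and enhancers. The series held 1 group with 2 biological replicates. Replicate 1 came from the pooled hindbrains of 109 embryos and replicate 2 from those of 88, both of mixed sex and of strain B6NCrl. No other tissue, stage or input library was among the samples, so the comparisons were those between the replicates, between parts of the genome and between lists of genes within this tissue. On the assembled chromosomes of mm10, replicate 1 had 44143 peaks covering 38.8 Mb and replicate 2 had 56235 peaks covering 37.2 Mb. The authors' list called on both replicates together (the pooled list) had 38365 peaks, and the part of it that they kept as replicated had 29905 peaks with a median width of 1006 bp over 37.6 Mb. The files gave no read totals, so the depth of each library is unknown, and the 95% Clopper-Pearson intervals below cover counting error only. Peaks, and genes, are not independent replicates.

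The 10 strongest H3K4me2 peaks by pooled fold lay at promoters, and each met a tall peak in both replicates. The highest pooled fold enrichment over control, 68.7, was at Egr1, an immediate early transcription factor gene (chromosome 18, 34859166 to 34863195), with 54.8 in replicate 1 and 53.9 in replicate 2. Specc1, which encodes a cytospin, followed with a pooled fold of 65.7 (62.1 in replicate 1 and 41.5 in replicate 2). Galnt3, a gene for an enzyme of mucin-type O-glycosylation, had a pooled fold of 61.8 (50.4 and 49.8). The other members of the 10 strongest peaks lay at the promoters of Map3k10, Sptb, 9130017K11Rik and Usp43, Col27a1, Gm9768 and Klhl21, the long non-coding RNA gene Lncpint, and Mms19, with pooled folds from 54.6 to 59.5.

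How far the replicates gave the same peaks was measured by overlap. Of the replicate 1 peaks, 71.3% (interval 70.8 to 71.7) were met by at least 1 bp of a replicate 2 peak, against 3.03% ± 0.0874 (SD of 100 shuffles of the peak positions within chromosomes). Of the replicate 2 peaks, 63.3% (62.9 to 63.7) were met in replicate 1, against 2.5% ± 0.0688 in shuffles. The Jaccard index of covered bases was 68.6%, against 0.785% ± 0.0314. No shuffle reached the observed values (one-sided permutation p = 0.0099, the smallest that 100 shuffles can give). Overlap was complete among strong peaks and partial among weak ones: every peak in the 4 highest fold deciles of replicate 1 and in the 3 highest of replicate 2 was met, while in the lowest decile 25.5% and 24.2% were, and the minimum in replicate 2 was 17.4%, in decile 3. With peaks at a −log10 q of 5 or more, the share of replicate 1 peaks met in replicate 2 was 88.5% and that of replicate 2 peaks met in replicate 1 was 95.3%. With at least 50% of the peak covered the shares were 64.1% and 59.1%, and with 50% of both peaks 55.8% and 43.8%.

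**Figure D1:**
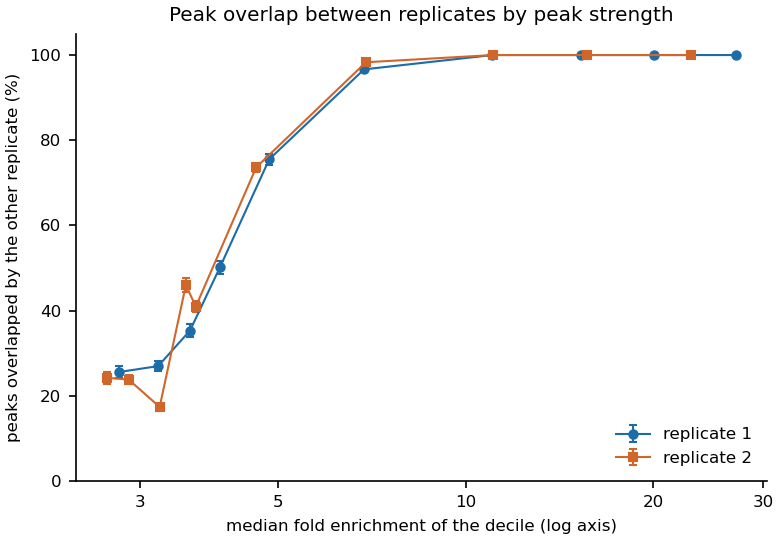
Share of each replicate's peaks overlapped by a peak of the other replicate (%, vertical axis) against the median fold enrichment of the fold decile (log axis), with 95% Clopper-Pearson intervals, which are mostly smaller than the points. All peaks in the deciles with a median fold above 11 were met, while in the lowest decile of replicate 1 the share was 25.5%.

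Peaks seen in a single replicate were weak and mostly away from promoters. The 12682 unmatched peaks of replicate 1 had a median fold of 3.33 and a median width of 215 bp, and 12.2% had their midpoint in a promoter, against 4.46% in shuffles. The 20658 unmatched peaks of replicate 2 had a median fold of 3.23 and a median width of 175 bp, with 9.46% in promoters, against 4.47% in shuffles. Among the 5 strongest unmatched peaks of replicate 1 were those at the promoters of Rps19bp1 (fold 8.30) and Nom1 (fold 8.15). The strongest unmatched peaks of replicate 2 included intronic ones 1548 bp from the Svop TSS (fold 7.51) and 3846 bp from that of S1pr2 (fold 7.24). The heights of the 31461 peaks shared by both replicates went together, with a Spearman correlation of 0.857 across peaks and a median ratio of replicate 1 to replicate 2 of 1.09 (5th to 95th percentile 0.583 to 1.71). The authors' replicated list kept 77.9% (77.5 to 78.4) of the pooled peaks. The 8460 pooled peaks outside it had a median fold of 3.1, against 11.8 for those in it.

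Promoters held more of the replicated peaks than any other class of sequence. By midpoint, 57.5% (56.9 to 58.1) of the 29905 peaks lay within 1 kb of a TSS, 13.1 times the 4.40% ± 0.120 (SD) of 100 shuffles. Introns held 22.3% of the peaks, against 41.2% in shuffles, and intergenic sequence held 15.1%, against 51.4%. Coding exons held 3.19%, against 1.18%, and 5′ UTRs 0.15%, against 0.0356%. Each of these shares lay outside all shuffles (one-sided permutation p = 0.0099, the smallest possible). The share in 3′ UTRs was 1.11%, against 1.25% in shuffles (permutation p = 0.0297), and that in non-coding exons 0.675%, against 0.596% (p = 0.0693). Promoter peaks were the tallest and widest of the large classes, with a median fold of 17.3 and a median width of 1359 bp, against 4.91 and 555 bp in introns and 5.66 and 589 bp in intergenic sequence. Replicate 1 alone had 45.2% of its peaks in promoters, replicate 2 alone 39.4% and the pooled list 48.2%. Among replicated peaks at or above the median fold of 11.8, the promoter share was 81.5%, with 9.23% in introns and 5.80% in intergenic sequence, and in the lists of the single replicates and the pooled list the shares in 3′ UTRs and in non-coding exons were above those in all shuffles. With promoters of 500 bp either side of the TSS, promoters held 40.9% and introns 34.0%.

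**Figure D2:**
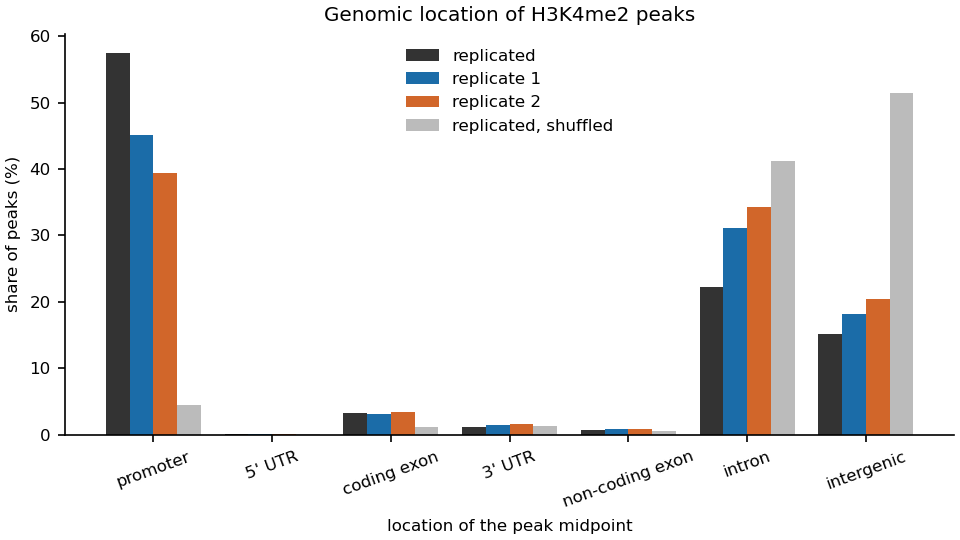
Share of peaks (%) with their midpoint in each class of annotated sequence, for the replicated list, for each replicate alone and for the replicated list shuffled within chromosomes (mean of 100 shuffles). The promoter bar of the replicated list stands at 57.5%, against 4.40% in shuffles.

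The genes that build the early brain nearly all carried H3K4me2 at their promoters, and those of blood, germline, liver and gut, and heart and muscle mostly did not. Of the 21938 protein-coding genes, 14219 (64.8%) had a replicated peak within 1 kb of a TSS, with the same call in both replicates for 98% of genes. All 25 neural stem and progenitor genes were marked, among them Sox2, a pluripotency and neural progenitor factor, Hes5, a Notch target, and Nes, the intermediate filament nestin (adjusted p = 1.26e-04 by Fisher's exact test over the 20 lists). The 25 general neuronal genes, such as Tubb3 (neuronal tubulin), Dcx and Snap25, were also all marked (adjusted Fisher's exact p = 1.26e-04). So were all 18 midbrain and isthmus genes (adjusted Fisher's exact p = 0.00152), 20 of 21 rhombomere and hindbrain patterning genes (0.00391), 24 of 25 forebrain regulators (0.00119) and 23 of 25 dorsoventral progenitor genes (0.00475). Lower but still above the other genes were 23 of 27 hindbrain neuron regulators (0.0330), 18 of 20 neural crest and mesenchyme genes (0.0245) and 21 of 24 retinoic acid and Shh signalling genes (0.0245). The members without a peak were Cyp26c1, Rax, Nkx2-2, Dbx1, Evx1, Evx2, Nkx6-3, Vsx2, Col3a1, Tcf21, Rbp1 and Aldh1a1. All 21 housekeeping and all 22 cell cycle genes were marked (adjusted Fisher's exact p = 3.98e-04 each).

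Lists of blood, germline, liver and gut, and heart and muscle genes fell below the other protein-coding genes. Of 20 blood and immune genes, 3 had a promoter peak (adjusted p = 6.54e-05 by Fisher's exact test), namely Epor, the erythropoietin receptor gene, Klf1, an erythroid transcription factor gene, and Gypa, a glycophorin gene, while Gata1 and the embryonic globin genes had none. Of 18 germline genes, Dazl and Dmc1 alone were marked (6.54e-05). Liver and gut had 4 of 20 (2.14e-04), which were Foxa1, Foxa3, Cdx1 and Pdx1, all transcription factor genes, and Alb, the serum albumin gene, had no peak. Heart and skeletal muscle had 6 of 20 (0.00355), with Myod1, the skeletal muscle determination gene, and Gata4 among the marked. Hox groups 9 to 13 had 5 of 16 (0.0114). The lists of late glia, at 6 of 15 (0.0673), and endothelium, at 8 of 15 (0.419), did not pass the test, nor did Hox groups 1 to 4, at 11 of 12 (0.0751), or Hox groups 5 to 8, at 10 of 11 (0.116). In all, 11 lists were called higher and 5 lower. With either replicate's list alone, both Hox lists were complete and were called higher (adjusted p from 0.0141 to 0.0256). Late glia were called lower at a −log10 q of 5 or more, and also without olfactory and vomeronasal receptors in the background. Against random genes matched on CpG content at the 5′-most TSS, the general neuronal list alone stayed higher, and the other 10 higher calls ended. Hox groups 9 to 13, liver and gut, and germline stayed lower, while the blood and the heart and muscle calls ended. In that permutation test, 7 of the 11 higher lists could not have passed with every member marked. The rhombomere, neural crest, and retinoic acid and Shh lists could have passed before adjustment but did not. At or above the median fold 5 lists were called higher.

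**Figure D3:**
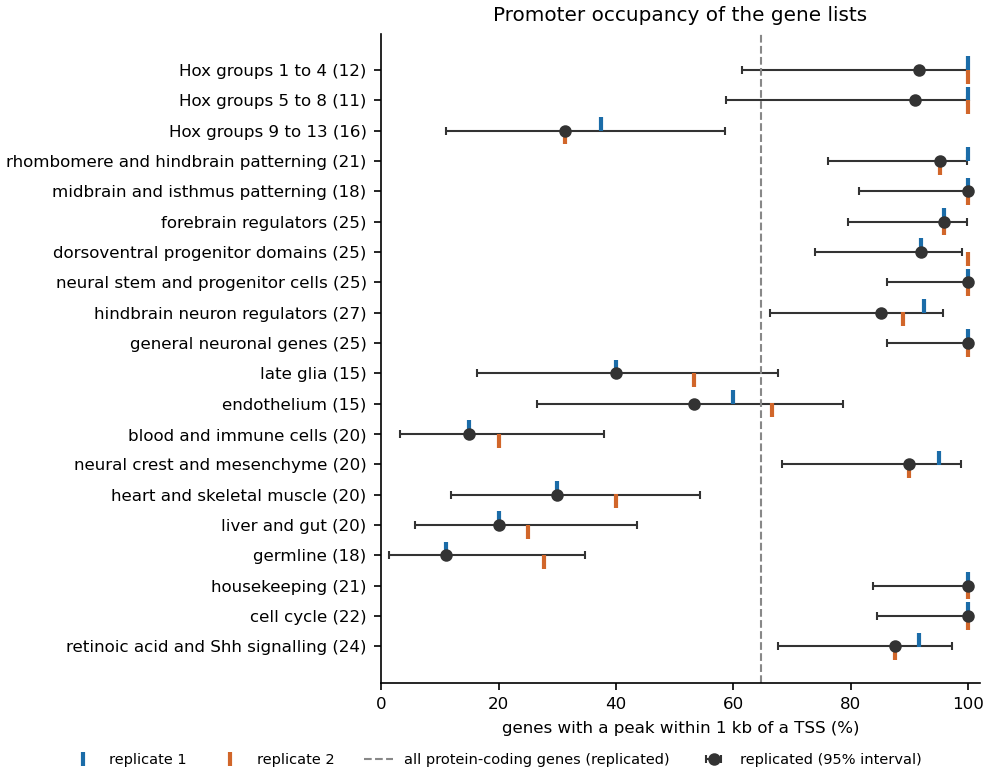
Share of the genes of each list (%, number of genes in brackets) with a peak within 1 kb of a TSS: points for the replicated list with 95% Clopper-Pearson intervals, ticks for each replicate, and a dashed line for all protein-coding genes at 64.8%. The neural, housekeeping and cell cycle lists lie to the right of the line, and blood, germline, liver and gut, heart and muscle, and Hox groups 9 to 13 to the left.

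H3K4me2 domains were broad at regulators of neural progenitors and of the hindbrain. In the 10 kb around the TSS (5 kb on each side), marked genes had on average 2284 bp under peaks. The 25 neural stem and progenitor genes had 6371 ± 2050 bp (SD across genes), led by Pou3f3 (9745 bp), Zic1 (9674 bp) and Pou3f2 (9190 bp), and every member was above the median of all marked genes. Marked genes of Hox groups 1 to 4 had 6184 ± 3386 bp (n = 11) and rhombomere and hindbrain patterning genes 6149 ± 2807 bp (n = 20). In the latter list, Meis2, a Hox cofactor gene, was covered over 10000 bp (10000 bp in replicate 1 and 9953 bp in replicate 2), Irx2 over 9833 bp and Irx3 over 9604 bp. Mafb and Egr2, which pattern rhombomeres, had 4943 bp and 3968 bp, and Gbx2, which sets the anterior border of the hindbrain, had 8582 bp. General neuronal genes had 5083 ± 2208 bp (n = 25), with Ebf3 at 9412 bp, Scrt1 at 8231 bp and Tubb3 at 6366 bp. Dorsoventral progenitor genes had 4724 ± 2307 bp (n = 23), with Pax3 at 9546 bp, Ptf1a at 3434 bp and Atoh1 at 3039 bp. Retinoic acid and Shh signalling genes had 4310 ± 1814 bp (n = 21), led by Ptch1, the Shh receptor gene, at 8258 bp, and Shh itself had 3831 bp. Each of these means was above those of 100000 random lists of marked genes (adjusted permutation p = 5.43e-05, from the smallest raw p that they can give, 2e-05).

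Smaller excesses were found for Hox groups 5 to 8 (4251 ± 2812 bp, n = 10, adjusted permutation p = 5.91e-04), midbrain and isthmus genes (3777 ± 2416 bp, n = 18, 9.5e-05), hindbrain neuron regulators (3708 ± 2326 bp, n = 23, 5.43e-05), cell cycle genes (3369 ± 1499 bp, n = 22, 0.00118) and housekeeping genes (3182 ± 1099 bp, n = 21, 0.00747). Within these lists, Lhx1 reached 9841 bp and En1, a midbrain and anterior hindbrain gene, 7873 bp, while Phox2b, a regulator of visceral motor neurons, had 2273 bp, Actb 2426 bp and Gapdh 4390 bp. Narrower than random lists were Hox groups 9 to 13 (1028 ± 239 bp, n = 5, adjusted permutation p = 0.00747), liver and gut (1032 ± 631 bp, n = 4, 0.0179) and heart and skeletal muscle (1307 ± 583 bp, n = 6, 0.0316). Forebrain regulators (2114 ± 1967 bp, n = 24, 0.555), neural crest and mesenchyme (2741 ± 1653 bp, n = 18, 0.167), late glia (1719 ± 1706 bp, n = 6, 0.271), endothelium (2051 ± 784 bp, n = 8, 0.643) and blood (1318 ± 436 bp, n = 3, 0.152) did not differ from random lists by the permutation test. The germline list, with 2 marked genes, was not tested, but with the list of replicate 2 alone it had 5 and was called narrower (379 ± 373 bp, adjusted permutation p = 5.71e-05). The 3 narrower calls ended with a window of 10 kb either side or with peaks at or above the median fold, where the broader calls for Hox groups 5 to 8, midbrain, hindbrain neuron and housekeeping genes ended as well. With a window of 2.5 kb either side, the broader calls for Hox groups 5 to 8, midbrain and hindbrain neuron genes ended (adjusted permutation p = 0.275, 0.167 and 0.195) and forebrain regulators were called narrower (1607 bp, 0.0301).

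**Figure D4:**
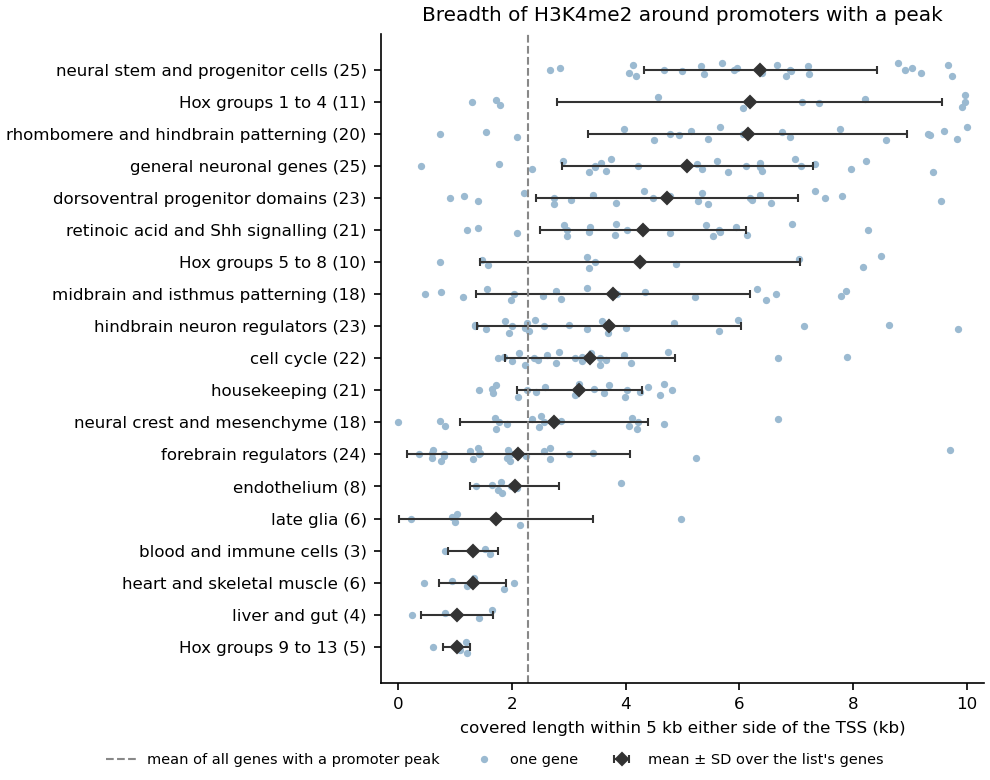
Length under replicated peaks within 5 kb either side of the TSS (kb) for each marked gene (dots), with the mean ± SD of each list (diamonds, number of genes in brackets) and the mean of all marked genes (dashed line). Neural stem and progenitor genes, Hox groups 1 to 4 and rhombomere genes have the highest means, from 6149 to 6371 bp.

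The Hox clusters, whose genes set position along the body axis, carried more H3K4me2 over groups 1 to 4 than over groups 9 to 13, although the mark did not follow the order gene by gene. Of Hox groups 1 to 4, 11 of 12 genes (91.7%) had a promoter peak, against 5 of 16 (31.3%) in groups 9 to 13 (two-sided Fisher's exact p = 0.00205). Mean covered length over all members was 5849 ± 3431 bp in groups 1 to 4 and 404 ± 512 bp in groups 9 to 13 (two-sided permutation p = 2e-05, the smallest possible). Hoxb4 (9973 bp), Hoxa2 (9962 bp), Hoxb3 (9923 bp) and Hoxb2 (8209 bp) were covered almost throughout their windows or over most of them, and Hoxa1 had 7101 bp. Hoxb1, the gene of rhombomere 4, had 1718 bp and Hoxd1 1798 bp, less than Hoxa5 (8486 bp) and Hoxb5 (8175 bp) of groups 5 to 8. Hoxd3 had 1304 bp around its 5′-most TSS and 63.7% of its body under peaks. Hoxa3 had no peak at its annotated basic TSS but 77.3% of its body, which spans Hoxa4, Hoxa5 and Hoxa6, under peaks, and with the TSSs of every annotated transcript all 12 genes of groups 1 to 4 were marked. Of the marked genes of groups 9 to 13, Hoxd13 had 1210 bp, Hoxa13 1183 bp, Hoxd9 1083 bp, Hoxb9 1045 bp and Hoxd11 617 bp, while Hoxa9, Hoxa10, Hoxa11, Hoxd10 and Hoxd12 had no promoter peak. From the lowest to the highest cluster, peaks covered 17.5% of Hoxc, 34.1% of Hoxd, 35.0% of Hoxb and 46.6% of Hoxa. Neighbouring Hox genes share windows and domains, so their values are not independent.

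**Figure D5:**
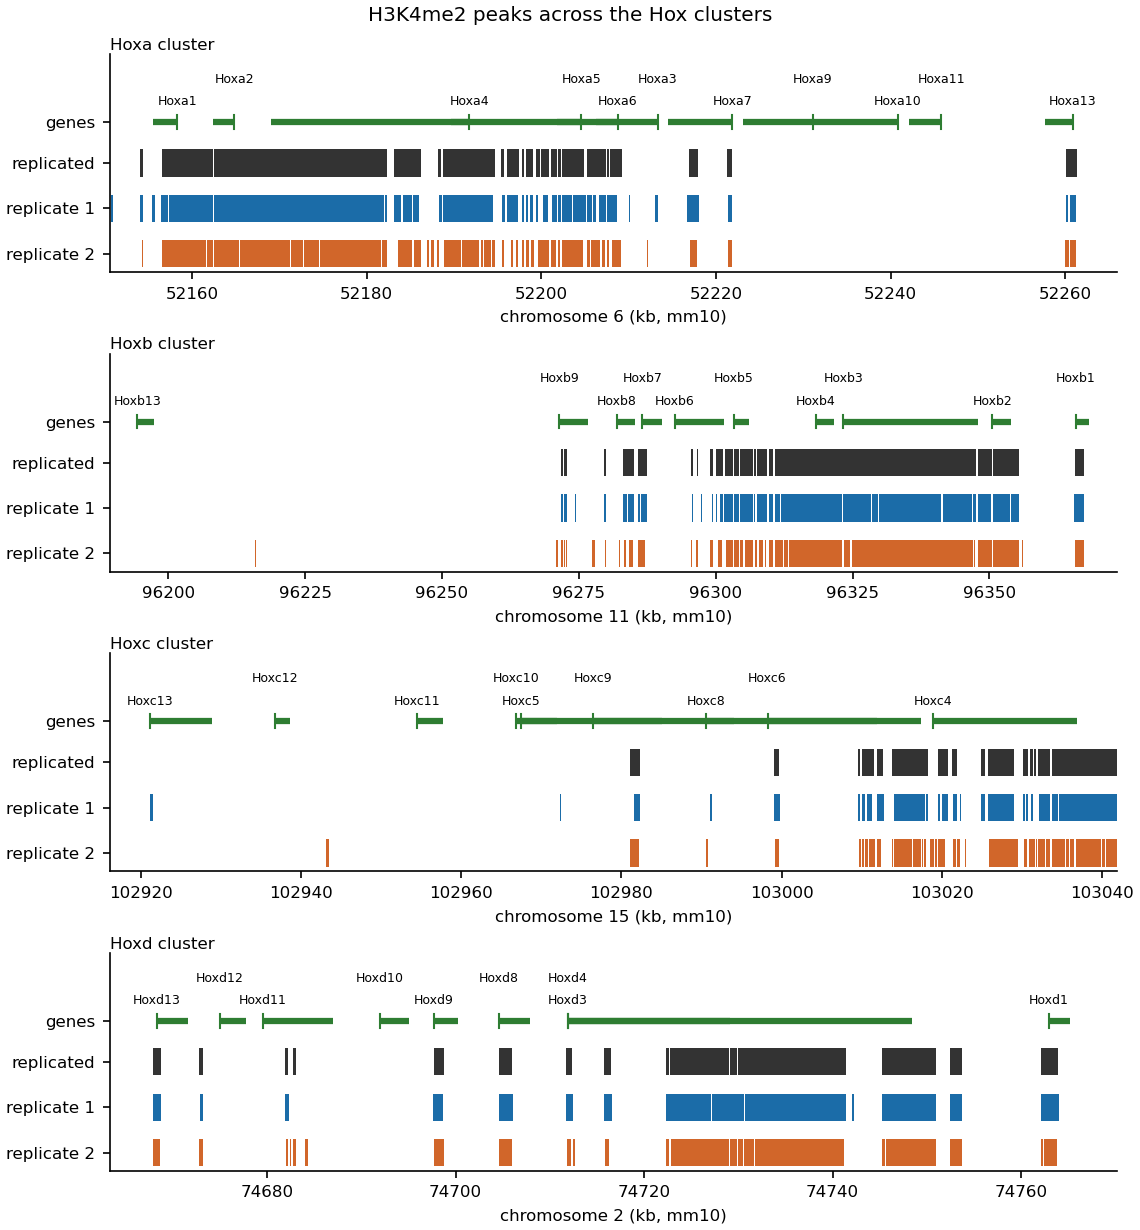
Positions of H3K4me2 peaks (boxes) along the Hoxa, Hoxb, Hoxc and Hoxd clusters on mm10 (kb), in the replicated list and each replicate, under the gene models (green bars, with ticks at the 5′-most end). The long domains cover the ends with Hoxa1 to Hoxa6, Hoxb2 to Hoxb5, Hoxc4 and the Hoxd3 and Hoxd4 bodies, and the groups 9 to 13 hold short peaks or none.

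Hindbrain and forebrain regulators were compared for regional identity of the dissected tissue. The hindbrain list held Meis2, Irx2, Irx3 and Efnb2 beside Mafb, Egr2 and Gbx2. Whether its members are confined to the hindbrain was not examined, so the contrast does not isolate regional identity. Promoter peaks were as frequent in the forebrain list (24 of 25, 96.0%) as in the rhombomere and hindbrain list (20 of 21, 95.2%; two-sided Fisher's exact p = 1), but domains were broader in the hindbrain list. Covered length over all members was 5870 ± 3021 bp (n = 21) in the hindbrain list and 2067 ± 1940 bp (n = 25) in the forebrain list, a difference of 3803 bp (two-sided permutation p = 6e-05). Replicate 1 alone gave a difference of 3782 bp and replicate 2 alone 3811 bp. Foxg1, a telencephalic gene, had 1443 bp, Otp 804 bp, Nkx2-1 602 bp, Hesx1 590 bp and Tbr1 362 bp, while Nr2f1 (9709 bp), Satb2 (5245 bp) and Dlx2 (3433 bp) led the forebrain list. Otx2, a forebrain and midbrain gene of the midbrain and isthmus list, had 749 bp. At or above the median fold, 90.5% of the hindbrain list but 40.0% of the forebrain list had a promoter peak (Fisher's exact p = 5.80e-04).

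Distal peaks, those over 2.5 kb from any TSS and thus possible enhancers by position, were counted around each gene. Pax2, a gene of the midbrain-hindbrain border, had 16 within 50 kb of its TSS (19 in replicate 1 and 24 in replicate 2), against a mean of 0.746 over all marked genes. Igdcc3 and Uncx had 13, Cbx8, Cxxc5 and En2 12, and Asic4, Foxp4, Gmppa and Pax3 11. Gmppa and Asic4 are neighbours on chromosome 1 (TSSs at 75435930 and 75450436), so their windows largely overlap and can hold the same peaks. By list, the mean was 5.70 ± 3.50 (SD) for marked genes of Hox groups 5 to 8, 4.61 ± 4.35 for midbrain and isthmus genes, 4.09 ± 4.06 for Hox groups 1 to 4 and 3.92 ± 2.84 for neural stem and progenitor genes. Windows of neighbouring Hox genes overlap and can hold the same distal peaks (Hoxa4, Hoxa5 and Hoxa6 had 10 each). The Hox means therefore rest on fewer separate regions than genes, which the permutation test did not take into account. Distal peaks were counted before merging, so pieces of a domain that also covers promoters can count as distal. Short replicated peaks between Hoxa4 and Hoxa5, for example, lay in the 21042 bp domain of Hoxa4 to Hoxa6. Distal counts and domain lengths there are not separate evidence. Dorsoventral progenitor (3.13), retinoic acid and Shh signalling (2.95), hindbrain neuron (2.78), general neuronal (2.2), rhombomere (2.05), forebrain (2.00) and neural crest (1.72) lists were also above random lists, which made 11 in all (adjusted permutation p from 5.43e-05 to 0.0257), and none was below. Hindbrain and forebrain lists did not differ from each other (2.10 ± 2.36 against 1.92 ± 1.93 over all members, two-sided permutation p = 0.833). The number of distal peaks varied with the list used, with a mean over marked genes of 1.43 in replicate 1 and 2.11 in replicate 2, and with replicate 2 alone the neural crest call ended (adjusted permutation p = 0.0592). At or above the median fold, only the neural stem and progenitor list (0.913) and the retinoic acid and Shh list (0.526) stayed above random lists.

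The longest domains lay in the Hox clusters and at other transcription factor genes such as Pou3f3, Nr2f2, Meis2 and Sox2. Replicated peaks merged over gaps of up to 1 kb gave 22578 domains with a median of 1450 bp, of which 75 reached 10 kb. The longest, 56490 bp on chromosome 11 (96298971 to 96355460), ran over the promoters of Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6, and replicate 1 peaks covered 91.1% of it and replicate 2 peaks 89.4%. Next were domains at Pou3f3, a POU factor gene of neural progenitors (31397 bp), at Hoxa1, Hoxa2 and 5730596B20Rik (29733 bp), and at Nr2f2, an orphan nuclear receptor gene (28282 bp). Domains at Pou3f2 (22484 bp), Hoxa4 to Hoxa6 (21042 bp), Mllt10, Skida1 and A930004D18Rik (21034 bp), Meis2 (20772 bp), Sox2 (19243 bp) and Gm28230 in the Hoxd cluster (19142 bp) completed the 20 genes with the longest domains. These 20 genes came from 10 distinct domains, so genes that share a domain are not separate cases. Hoxd4, with its TSS at 74721978, shared the Gm28230 domain, which starts at 74722272. It was left out of the 20 only because ties were ordered by symbol, and the count of list members depends on that cut. Of the 20 genes, 14 were on the fixed lists, whose members made up 2.05% of the genes with a promoter domain. With no gaps merged 8 of the 20 genes stayed among the 20 longest, with gaps of up to 3 kb 13 did, and at or above the median fold 12 did.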

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

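The tests on CpG-matched genes and CpG deciles, on shared Hox domains and on Hox folds were chosen only after the list results had been seen, as was the check of whether full lists could pass, while the stricter −log10 q was set beforehand. Outside the assembled chromosomes, which no comparison used, the replicated list held 11 peaks on 5 contigs, with folds from 1.91 to 7.71 and widths from 368 to 1389 bp (5 on contigs assigned to chromosome X, 3 to chromosome 4 and 3 unplaced). Replicate 1 had 14 such peaks and replicate 2 had 15. No control list was among the files to compare them with.

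Lists of brain, housekeeping and cell cycle genes were above other genes in promoter occupancy, and 4 lists of other tissues were below. Against random genes matched on promoter CpG content, 2 of the 4 lists of other tissues stayed lower: germline (11.1%, against 60.7% in matched genes, adjusted permutation p = 1.33e-04) and liver and gut (20.0%, against 44.9%, adjusted permutation p = 0.0204). This argues against promoter CpG content as the whole cause for those lists, and the same held for Hox groups 9 to 13 (31.3%, against 94.5%). For blood (15.0%, against 21.9%) and heart and muscle (30.0%, against 33.7%) the call ended because matched genes were nearly as rarely marked, while of the 11 lists called higher 1, general neuronal genes (100%, against 76.3%), stayed so. That count does not decide for promoter CpG content in the others, because 7 of the 11 lists could not have passed with every member marked (neural stem and progenitor genes, all marked, against 93.2%, permutation p = 0.139). Of those able to pass, neural crest kept most of its excess (90%, against 71.8% in matched and 64.8% in other genes, adjusted permutation p = 0.0758). Rhombomere (95.2%, against 85.4% in matched genes) and retinoic acid and Shh genes (87.5%, against 80.4%) kept less of theirs. Dorsoventral (92.0%, against 92.1%) and hindbrain neuron genes (85.2%, against 91.2%) had no excess left. Promoter CpG content thus stays open for the lists whose calls ended, and no biological explanation was tested, since the design has 1 group. The CpG ratio was taken at the 5′-most TSS, while a peak at any TSS counted as marked. Matching can therefore misjudge genes with further TSSs, and the general neuronal call was not checked for this.

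Rhombomere and hindbrain genes had broader domains than forebrain regulators, by 3803 bp, although promoter peaks were as frequent in both lists. After the mean of each gene's CpG decile was subtracted, the difference was 3832 bp (permutation p = 2e-05, the smallest possible). This argues against the CpG ratio within 500 bp of the 5′-most TSS as the cause. CpG content over the rest of the breadth window was not measured, so it stays open. With a −log10 q of 5 or more, 84.0% of the forebrain genes still had a promoter peak, against 64.1% of all protein-coding genes. Most marked forebrain promoters thus did not rest on peaks just past the authors' threshold, and the difference in breadth was 3885 bp with those peaks alone. The share cannot decide on weaker forebrain peaks in general, because it does not measure breadth and the filter removed few genes. Marked forebrain genes went from 24 to 21, and all marked genes from 14219 to 14065. At or above the median fold, the forebrain share was 40.0%, against 56.0% of all protein-coding genes, so forebrain promoters were less often among the tall peaks. The 10 that remained had 2315 ± 1448 bp against 5878 ± 2859 bp for 19 hindbrain genes. Regional identity of the tissue may underlie the difference, but with no forebrain sample it stays an untested hypothesis. The make-up of the lists may also do so, since members of the hindbrain list were not checked for use in other regions.

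Hox groups 5 to 8, more often used behind the hindbrain, had a peak at 10 of 11 promoters. Spread from the domains of groups 1 to 4 is a candidate explanation: 50% of the marked promoters (Hoxa5, Hoxa6, Hoxb5, Hoxb6 and Hoxc5) lay in a merged domain that also covered a promoter of groups 1 to 4, exactly the share named in advance as its lower bound, and the other 5 (Hoxa7, Hoxb7, Hoxb8, Hoxc6 and Hoxd8) did not. The Hoxc5 domain ended at 103018277, short of the Hoxc4 TSS at 103018934 though within 1 kb of it. Without Hoxc5 the share would be under the bound. It also rests on merging over gaps of up to 1 kb and was not recomputed with other gaps. Before merging, the replicated peak at the Hoxa4 promoter ended at 52194693 and that at the Hoxa5 promoter started at 52202342. The promoters of Hoxb5 and Hoxb4 likewise lay under separate peaks. The share therefore cannot decide on spread. Tissue from behind the hindbrain in the dissection could also give such peaks. Their mean fold was below that of groups 1 to 4 in both replicates (6.6 against 14.8 in replicate 1, permutation p = 6.8e-04, and 8.68 against 14 in replicate 2, permutation p = 0.0494), but 2 of the 4 group 9 promoters carried a peak, fewer than that explanation had been set to need, and no value excluded it, so it stays open. These explanations cannot be told apart from use of the genes in the caudal hindbrain itself, because the series holds no sample of neighbouring tissue.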

How the results depend on the processing

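The tests with genes matched on CpG content, the best-covered TSS, the TSSs of every transcript, shuffles without assembly gaps and the recount by 50% of either peak were chosen only after the data had been seen. Results were recomputed under 731 pairs of a result and an alternative. Of the main values and counts, 117 kept their direction and side of the threshold, 15 moved and 6 reversed, and for single lists and classes 508 kept both, 42 lost a call, 14 gained one, 3 moved and 26 reversed. Unless a cause is named below, the cause was not tested. No paired analysis was possible because the series has 1 group. Overlap, the replicated share and the correlation of folds need both replicates, so they have no value without either.

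The replicated share of pooled peaks was 99.4% at a −log10 q of 5 or more, 100% at or above the median fold, and by recount 69.3% (50% of the pooled peak covered in both replicates) and 73.8% (50% of either peak). The correlation of folds was 0.925 with 50% of both peaks covered, 0.843 at −log10 q of 5 or more and 0.850 at or above the median fold. In 3′ UTRs the share was above shuffles without either replicate (1.46% to 1.65%) and in the pooled list (1.39%), and with 500 bp promoters it was within them (1.29%, against 1.28%). In non-coding exons it was above all shuffles without either replicate (0.774% to 0.795%), in the pooled list (0.818%) and with 500 bp promoters (1.23%), below them at or above the median fold (0.340%), and below their mean but within their range at −log10 q of 5 or more (0.571%) and with 2.5 kb promoters (0.324%).

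At or above the median fold, where fewer peaks remain, promoter occupancy turned to or below that of other genes for Hox groups 5 to 8 (27.3%), forebrain (40.0%), dorsoventral (56.0%) and hindbrain neuron genes (48.1%), and 5 lists were called higher. Breadth turned for Hox groups 5 to 8 (1852 bp), forebrain (2315 bp) and neural crest (1699 bp), with 7 lists called broader and 0 narrower, and the mean of distal peaks was 0 for hindbrain neuron, endothelium and blood genes, with 2 lists called higher. Against CpG-matched genes, the dorsoventral (92.0%) and hindbrain neuron (85.2%) lists lay below their matched levels, and 1 list was called higher and 3 lower, in a test that 7 of the 11 higher lists could not pass. At −log10 q of 5 or more 1 list was called narrower, and with a 10 kb breadth window 0 were, while forebrain (2984 bp) and blood (2882 bp) moved above the mean of random lists, with no call. The narrower call for liver and gut ended in the pooled list and that for heart and muscle against CpG-matched genes. Without either replicate, endothelium occupancy ranged from 60% to 66.7%, and mean distal peaks from 1.90 to 2.11 for endothelium, 1.67 to 2.00 for blood and 1.33 to 3.13 for heart and muscle, which also reversed with a 100 kb window (1.33).

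The hindbrain minus forebrain difference in occupancy, −0.762 points in the replicated list, ranged from −0.762 to 4.00 points without either replicate, and was 4.00 in the pooled list and with 2.5 kb promoters, 6.48 at −log10 q of 5 or more and 50.5 at or above the median fold, where the difference in distal peaks was −0.154. The difference in breadth kept its direction and its call under every alternative run, from 3775 to 4229 bp, as did the breadth and occupancy differences between Hox groups 1 to 4 and 9 to 13. Neither breadth contrast was recomputed with breadth windows of 2.5 or 10 kb. The higher occupancy of hindbrain neuron genes was lost at −log10 q of 5 or more, and that of hindbrain neuron and neural crest genes with 500 bp promoters and without olfactory and vomeronasal receptors in the background, where the retinoic acid and Shh call ended too. With the 5′-most TSS alone the forebrain and neural crest calls ended.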

Other observations

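All tests in this part, on gene families grouped by symbol, on clustered protocadherins and on summit positions, were chosen only after the data had been seen. Beyond the fixed lists, 42 gene families were compared with other protein-coding genes, with adjustment over the families: 14 were called higher in promoter occupancy and 11 lower, and of 37 tested for breadth 14 were broader and 7 narrower. All 5 Zic genes, which encode zinc finger factors of the dorsal neural tube, were marked and had 7342 ± 2188 bp under peaks (SD, adjusted permutation p = 1.23e-04), and the 6 Irx genes had 6963 ± 3230 bp (1.23e-04). Of the Sox genes 18 of 19 were marked, with 4248 ± 2126 bp. Among families of axon guidance genes, all 20 semaphorins and all 14 Eph receptors were marked, and so were all 8 ephrins and 8 of 9 plexins (all but Plxnb3), although occupancy of the ephrins and plexins did not pass (adjusted Fisher's exact p = 0.0857 and 0.215). The ephrins were broad (4717 ± 1171 bp, n = 8, adjusted permutation p = 4.63e-04), led by Efnb2 at 6067 bp. All 20 ionotropic glutamate receptor genes had a promoter peak (adjusted Fisher's exact p = 5.87e-04). Of 19 GABA-A receptor genes 14 did, a share not called different from other genes (73.7%, against 64.8%, adjusted Fisher's exact p = 0.546). The marked GABA-A receptor genes had narrow domains (1466 ± 655 bp, adjusted permutation p = 0.0106).

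All 78 mitochondrial ribosomal protein genes and all 37 complex I genes were marked, with no call for breadth (2046 ± 878 bp and 2090 ± 852 bp, adjusted permutation p = 0.131 and 0.438). Cytosolic ribosomal protein genes were marked at 76 of 79 and were called broader (2650 ± 967 bp, adjusted permutation p = 0.0358). Replication-dependent histone genes were marked at 59 of 67 promoters with 4010 ± 1633 bp, though windows of neighbouring histone genes overlap and sharing of reads between them was not examined, so single genes are uncertain. Epithelial and immune families were low, with keratins at 6 of 53, interleukins at 6 of 33 and claudins at 11 of 33. Of 1134 olfactory receptor genes 3 had a peak, and of 330 vomeronasal receptor genes 1 did. Mean promoter CpG ratios, observed to expected, were 0.335 for keratins, 0.262 for interleukins, 0.349 for claudins and 0.114 for olfactory receptors. They were 0.745 for mitochondrial ribosomal protein genes and 0.705 for complex I genes. The families were not compared with CpG-matched genes, so their calls are not separated from promoter CpG content.

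The clustered protocadherins, cell surface genes chosen in combinations by neurons, lay at the other end from most neuronal genes (chromosome 18, TSSs from 36930184 to 37819513). Of 56 genes, 10 had a replicated promoter peak, and 13 did in each replicate alone. In the alpha cluster these were Pcdhac1 and Pcdhac2 of 13 genes (adjusted Fisher's exact p = 8.53e-04), in the beta cluster none of 22 (4.79e-10), and in the gamma cluster 8 of 21 (0.0327), with Pcdhgc3 the broadest at 4591 bp. The gamma cluster had 10 marked genes in replicate 1 alone and 11 in replicate 2 alone. Sharing of reads between similar protocadherins was not examined, so single genes are uncertain. Their median promoter CpG ratio, observed to expected, was 0.558, against 0.571 for all protein-coding genes and 0.724 for marked genes, but the clusters differed, with means of 0.676 for alpha, 0.357 for beta and 0.603 for gamma.

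At 6320 marked genes with a single TSS, the summit of the strongest promoter peak lay a median of 355 bp downstream of the TSS (360 bp in replicate 1 and 339 bp in replicate 2). It was downstream in 78.1% of genes and within 100 bp in 6.84%. Replicated peaks numbered 19.6 per Mb on chromosome 11, the highest of the chromosomes, 5.55 per Mb on chromosome X and 5 in all on chromosome Y.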
